A study of Homo sapiens with 4 samples.

How the data were processed

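Total RNA from 4 human cell cultures was profiled on 1-colour (Cy3) Illumina-type bead arrays, with 8 arrays in all. H9 is a human embryonic stem cell line and NCCIT is an embryonal carcinoma line, and each was measured on 3 arrays. HEF stands here for fibroblast-like cells grown out of differentiated H9 cells, and HFF for a human foreskin fibroblast line, and each of these was measured on 1 array. Per the labels, RNA was amplified linearly from 300 ng of total RNA with an in vitro transcription of 6 h. NCCIT and HFF were grown with 10% fetal calf serum, H9 in medium conditioned by mouse embryonic fibroblasts on Matrigel, and HEF in a medium that held serum.

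The deposited intensity values of each array are average signals per probe on the scanner scale, per the file headers, and BeadStudio 1.0 is the software named in the submitters' processing notes. No background had been subtracted and the arrays had not been brought to a common scale: the lowest signals lay between 66.0 and 87.0, and the median signals between 107.7 and 163.0. The deposited detection score runs from 0 to 1 and rises with the signal, per the file headers and the values, so 1 minus the score was taken as a detection p-value. A spread of the beads behind each signal was also deposited and served only to describe the arrays. A table of the whole series holds the authors' processed intensity values, 1 column per cell line, and per the labels the H9 and NCCIT columns are averages of 3 cultures or hybridisations. That table ranks probes as the array signals do (Spearman correlations of 1.0 after rounding, across probes with a value), leaves between 53.0% and 54.6% of the probes without a value, and has column medians between 298.0 and 309.3. Its exact scale, its normalization and the cut-off for leaving a value out are not given in the sources used here, and it was used only as an alternative.

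The arrays carry 24350 probes with sequence-record identifiers and 4 control rows, which were left out of normalization and tests. The files and the reference table used here do not pair these identifiers with gene symbols. Gene lists and gene names fixed before the data were examined could therefore not be looked up or tested, and no gene is named. Probes were not collapsed to genes as had been planned, and counts are of probes.

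Signals were background-corrected with the nec function of limma 3.58.1 in R 4.3.3 (normexp with the mean and SD of negative controls inferred from the detection p-values, offset 16), then quantile-normalized between the 8 arrays and put on the log2 scale. A probe was tested if its detection p was at most 0.01 on every array of at least 1 of the 4 cell lines, which left 12737 probes. limma's lmFit and eBayes fitted 1 mean per cell line to all 8 arrays. The residual spread has 4 degrees of freedom and comes from the H9 and NCCIT arrays alone, so in tests with HEF or HFF the lone array is assumed to vary like the H9 and NCCIT cultures. P-values are two-sided and Benjamini-Hochberg adjusted over the tested probes, and a probe was called at an adjusted p below 0.05. For the contrast of both fibroblast-like cultures with both pluripotent lines, a called probe also had to lie beyond all 6 H9 and NCCIT arrays on both fibroblast-like arrays. HEF was not tested against HFF, which would set 1 array against 1.

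The labels describe the H9 and NCCIT files as replicate cultures or hybridisations. P-values measure only the spread between these arrays, which may be partly technical, and the precision is limited by the number of arrays. No slide or scan date is given in the files, so an array batch could not be tested. The replicate numbers in the file names were checked as a pairing: correlations of the deviations of same-numbered arrays from their line means were -0.056, -0.112 and 0.038, so no pairing was used.

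Individual probes were chosen by a rule fixed before the data were examined: the largest fitted log2 changes in each direction among called probes whose sides do not overlap and which were detected on every array of the higher side. The rule had been written for named genes and took 8 per direction. It was applied to probes, and at most 2 are given per direction because no gene name can be attached. Sex-linked transcripts cannot be recognised without names, so a probe that might be one is not given. A probe detected on no array of the lower side has only a bound there, so the fitted change served to choose it and gives no rank among such probes. The bound was computed as the mean of the higher side over the mean, on the lower side, of the higher of each array's lowest detected signal and the probe's own signal. Such a bound holds for the background correction it was computed with, and is given without that correction as well. The tests were run on simulated data before use, with the real probes' means and spreads (12737 probes). For NCCIT versus H9, 86.0% of probes changed 2-fold and 100.0% of those changed 4-fold were recovered. For HEF versus H9 the shares were 69.0% and 96.0%, and for the fibroblast-like cultures versus the pluripotent lines they were 94.0% and 99.0%. Unchanged probes called by mistake numbered 9, 20 and 30 in these 3 comparisons. In the simulation only a small part of the probes changed, and independent normal noise was added after normalization. Each probe had the same spread on every array, HEF and HFF included. Far more probes were called in the real data, so these shares and counts are not error rates of the real tests.

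Alternatives fixed before the data were examined were no background correction (signals floored at 16), normexp by saddle point, median scaling, no detection filter, probes detected on all 8 arrays, an intensity trend in eBayes, averaging probes of a sequence record, leaving out each H9 or NCCIT array, other sets of arrays in the fit, a 2-fold threshold, 1 value per cell line, a replicate block and the authors' processed values.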

Results

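Transcript levels were compared between 4 human cell cultures: H9 embryonic stem cells, NCCIT embryonal carcinoma cells (a line from a germ cell tumour), fibroblast-like cells derived from H9 (HEF), and foreskin fibroblasts (HFF). H9 and NCCIT were each measured on 3 arrays, HEF and HFF on 1 array each. NCCIT cells were more than 90% undifferentiated by OCT4 staining, per the labels. Of 24350 probes, between 10214 and 10828 were detected per array (detection p at most 0.01, at which chance gives about 244). A total of 12737 probes (52.3%) were detected on every array of at least 1 cell line and were tested, 7829 were detected on all 8 arrays, and 10682 were detected on none. Probes are identified below by sequence-record number, because the sources used here give no gene symbols for them.

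Replicate arrays of the same line were close to each other. Pairs of H9 arrays differed by 2-fold or more at 3 to 31 of the 12737 tested probes, and pairs of NCCIT arrays at 18 to 21. The median absolute log2 difference between replicate arrays was 0.13 to 0.15 for H9 and 0.10 to 0.13 for NCCIT. No 2 arrays held identical signals, and each was counted as a replicate.

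The 4 cultures fell into a pluripotent pair and a fibroblast-like pair. The first principal component (53.1% of the variance) placed H9 and NCCIT on one side and HEF and HFF on the other, and the second (37.8%) separated H9 from NCCIT. HEF and HFF were the most alike of the cell lines, with a correlation of 0.91 across probes and a median absolute log2 difference of 0.34. H9 and NCCIT correlated at 0.83 (mean of 9 array pairs), with a median absolute log2 difference of 0.63. HEF lay farther from its parent line H9 (mean correlation 0.690 ± 0.0006, SD over 3 array pairs that share the HEF array) than from NCCIT (0.704 ± 0.0012), and 5936 against 5546 probes differed 2-fold or more per array pair on average. HFF likewise correlated at 0.707 with H9 and at 0.720 with NCCIT, so this order is not particular to HEF. H9 alone was grown in conditioned medium on Matrigel, while NCCIT, HEF and HFF were grown with serum. Line and culture medium therefore cannot be told apart here, nor in the comparisons of NCCIT, HEF and HFF with H9 below. These correlations are across probes, which are not independent replicates.

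**Figure D1:**
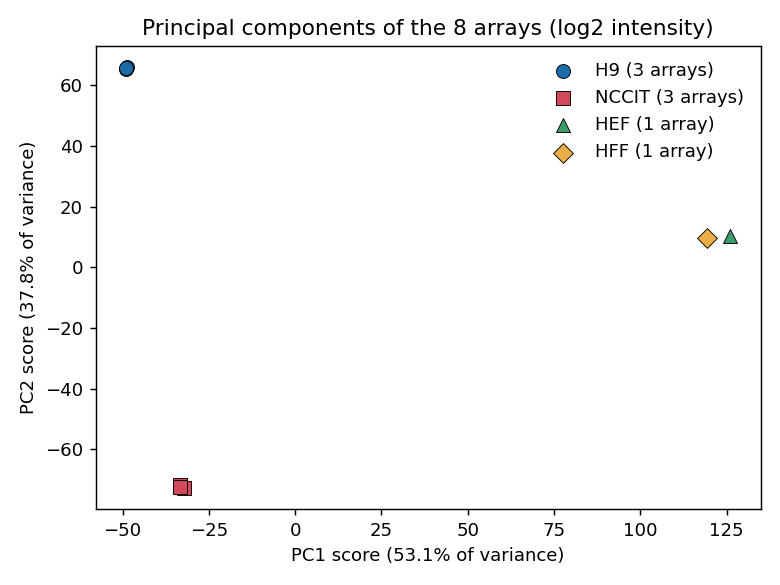
Scores of the 8 arrays on the first 2 principal components of the normalized log2 intensities of 12737 probes; each point is an array, and PC1 and PC2 hold 53.1% and 37.8% of the variance. The 3 arrays of H9 and the 3 arrays of NCCIT each lie together, and HEF and HFF lie side by side at PC1 scores of 126.1 and 119.4.

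The comparison of NCCIT with H9 asks how an embryonal carcinoma line differs from an embryonic stem cell line. At least 2-fold differences were called at 3945 probes, 1906 of them higher in NCCIT and 2039 higher in H9. Changes of 8-fold or more were called at 247 probes higher in NCCIT and 143 higher in H9. Many differences were between a detected and an undetected transcript. Of the 4406 probes called higher in NCCIT, 791 (18.0%) were detected on every NCCIT array and on no H9 array. Of the 5011 called lower, 883 (17.6%) were detected on every H9 array and on no NCCIT array. Among the large rises in NCCIT was that of probe GI_31542662-S, at a mean log2 intensity of 13.89 ± 0.04 (SD, n = 3) in NCCIT and 4.68 ± 0.06 (SD, n = 3) in H9, at least 354-fold (limma adjusted p = 2.5e-11). It was not detected in H9, and its log2 intensity was 4.75 in HEF and 4.85 in HFF. Probe GI_29540556-A was at least 168-fold higher in NCCIT (limma adjusted p = 4.09e-11) and, unlike the first, also read high in HEF (10.80) and HFF (9.53). Among the large falls was that of GI_24497516-S, not detected in NCCIT and at least 90.2-fold lower there (limma adjusted p = 2.23e-10).

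Without the 2-fold limit, 9417 of the 12737 probes (73.9%) were called by limma between NCCIT and H9, 4406 higher and 5011 lower in NCCIT. Both the numbers and their split depend on the processing: median scaling in place of quantile normalization gave 3426 higher and 6096 lower, or 1450 and 2943 at 2-fold or more, and moved the median log2 change of all tested probes from -0.05 to -0.25. Median scaling used the median of all probes on an array, which lay below the lowest detected signal on every array. It therefore aligned the background more than the signal of detected transcripts, here and in the comparisons below. Without background correction 1878 probes were called at 2-fold or more, 983 higher and 895 lower, 78 and 26 at 8-fold or more, and the bounds of the 3 probes became 110.0-fold, 52.4-fold and 29.5-fold. At 8-fold or more, median scaling gave 209 higher and 202 lower, saddle-point normexp 183 and 87, and probes detected on all 8 arrays 55 and 20.

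HEF cells against H9 show what differed between a fibroblast-like derivative and its parent line. At least 2-fold differences were called at 5916 probes, 2822 higher and 3094 lower in HEF. Changes of 8-fold or more were called at 572 probes higher and 364 lower in HEF. Among all probes called higher in HEF, 1153 of 4508 (25.6%) were detected in HEF and on no H9 array. Of the 5196 called lower, 1346 (25.9%) were detected on every H9 array and not in HEF. Probe GI_4507466-S rose at least 696-fold, from a log2 intensity of 4.62 ± 0.06 (SD, n = 3) in H9 to 14.87 in HEF (limma adjusted p = 2.31e-10), and read 14.41 in HFF. Probe GI_14719826-S rose at least 621-fold (limma adjusted p = 2.31e-10) and read 14.15 in HFF. Among the large falls were those of GI_24497516-S, at least 88.1-fold lower in HEF (limma adjusted p = 1.71e-09), and GI_22547196-S, at least 76.4-fold lower (limma adjusted p = 6.28e-10), neither of them detected in HEF. HEF has 1 array, so these p-values carry no variation between HEF cultures or derivations. Median scaling gave 2433 higher and 3782 lower at 2-fold or more, and 512 and 449 at 8-fold or more. Without background correction 3545 probes were called at 2-fold or more, 245 were higher and 78 lower at 8-fold or more, and the bounds became 216-fold, 192-fold, 29.2-fold and 25.4-fold in the order given; probes detected on all 8 arrays gave 187 and 109 at 8-fold or more.

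A common set of transcripts separated both fibroblast-like cultures from both pluripotent lines. Both HEF and HFF lay beyond all 6 pluripotent arrays, with an adjusted p below 0.05 for the contrast of means and an average change of at least 2-fold, at 2075 probes that were higher and 2301 that were lower in the fibroblast-like cultures. At 8-fold or more there were 446 higher and 164 lower. Probe GI_21536289-S was at least 553-fold higher in the fibroblast-like cultures (limma adjusted p = 1.75e-10), with readings of 14.60 in HEF and 14.53 in HFF against 4.78 ± 0.10 in H9 and 4.93 ± 0.37 in NCCIT (SD, n = 3 each). Probe GI_14719826-S was at least 500-fold higher (limma adjusted p = 1.61e-11). Of the probes that were lower, GI_22547196-S was at least 37.1-fold lower (limma adjusted p = 1.03e-10) and GI_13899240-S at least 34.3-fold lower (limma adjusted p = 1.02e-10). With no fold limit 6766 probes met the criteria, and with 1 value per cell line, which sets 2 lines against 2, limma called 285, 221 higher and 64 lower in the fibroblast-like cultures. In that fit limma's adjusted p was 0.0175 for GI_21536289-S, 0.0175 for GI_14719826-S, 0.0416 for GI_22547196-S and 0.0211 for GI_13899240-S, since the smaller values above rest on the spread between arrays of H9 and NCCIT. Without background correction 1313 probes were higher and 1278 lower at 2-fold or more, 181 and 25 at 8-fold or more, and the bounds became 174-fold, 158-fold, 13.1-fold and 12.0-fold in the order given. Median scaling gave 1775 higher and 2654 lower at 2-fold or more, and 395 and 180 at 8-fold or more. At 8-fold or more, saddle-point normexp gave 334 higher and 83 lower, and probes detected on all 8 arrays 111 and 35.

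Detection divided the cultures in the same way. Restricting to probes detected on all or none of the arrays of each line, 450 were detected in H9 and NCCIT alone and 406 in HEF and HFF alone. The mixed pairs shared fewer: 97 probes were detected in H9 and HEF alone, 73 in H9 and HFF alone, 85 in NCCIT and HEF alone, and 55 in NCCIT and HFF alone. H9 alone had 433 probes, NCCIT 401, HEF 286 and HFF 259. Transcripts missing from a single line numbered 250 for H9, 281 for NCCIT, 258 for HEF and 264 for HFF. A line with 3 arrays had to detect a probe 3 times and a line with 1 array once, so the sets of H9 and NCCIT are the stricter ones. Over all probes chance gives about 244 detections per array, so part of the HEF and HFF sets may be chance detections.

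**Figure D2:**
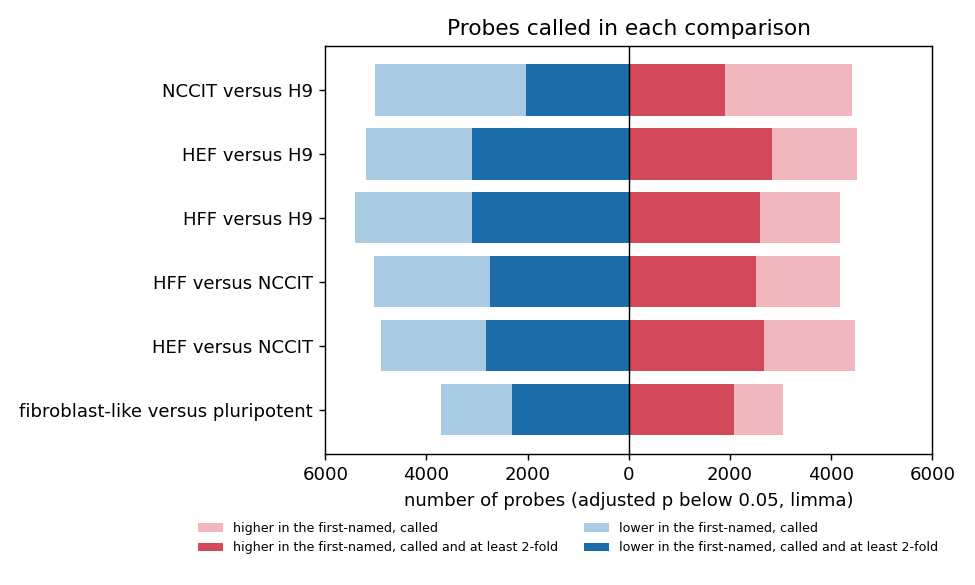
Number of probes called by limma (adjusted p below 0.05) per comparison, higher in the first-named cells to the right and lower to the left; pale bars show all called probes and dark bars those that also changed at least 2-fold. The fibroblast-like cultures differ from either pluripotent line at 5246 to 5916 probes of 2-fold or more, and NCCIT from H9 at 3945.

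The other pairs of a fibroblast-like with a pluripotent culture gave similar numbers. Between HFF and H9, 2595 probes were called at least 2-fold higher in HFF and 3105 lower (2108 and 4178 with median scaling, 1616 and 1683 without background correction). HFF against NCCIT gave 2507 higher and 2739 lower, and HEF against NCCIT 2672 higher and 2820 lower. The order of higher and lower turned for HEF against NCCIT with median scaling (2782 and 2640), and without background correction for HEF (1624 and 1614) and HFF (1496 and 1473) against NCCIT. With no fold limit, H9 was called higher than each of the other 3 cultures at 2809 of 12737 tested probes and lower at 1861. NCCIT was called higher than each of the others at 2113 and lower at 1690. Most tested probes were called in each pair behind these counts, so large counts were to be foreseen. The counts come from the reported setting only, and median scaling moved the split of higher and lower in those pairs.

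The change from H9 to HEF and the difference of HFF from NCCIT share no array and can be set against each other. Their log2 changes correlated across the 12737 probes with Pearson's r = 0.56 and Spearman's rho = 0.55. Simulated arrays without any change gave -0.03, but their lines do not differ at all, so that value is no baseline for lines that differ. Of the 3060 probes that differed at least 2-fold in both, 2795 (91.3%) went the same way. The swapped pairing, HFF minus H9 with HEF minus NCCIT, gave r = 0.56, and 2820 of 3102 such probes (90.9%) went the same way. The agreement is therefore not particular to the derivation of HEF from H9. Of the 2507 probes at least 2-fold higher in HFF than in NCCIT, 1799 (71.8%) were also called higher in HEF than in H9, 238 were called lower and 470 were not called. Of the 2739 that were lower, 1866 (68.1%) were also called lower in HEF, 309 were called higher and 564 were not called. Called probes coincided more than independent lists of those sizes would: 2687 were higher in both against 1474.1 for independent lists, and 3244 were lower in both against 2053.2. Both lists rest on the same estimate of spread for each probe, which by itself raises their overlap. Fewer were called in opposite directions, 1255 against 3480.4.

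HEF and HFF, the 2 fibroblast-like cultures, differed by 2-fold or more at 1919 probes detected in the higher of the 2, and replicate arrays of 1 line differed at 3 to 31. Of these, 893 were higher in HEF and 1026 higher in HFF, an order that turned with median scaling (1006 and 885), on probes detected on all 8 arrays (340 and 310) and in the authors' deposited table (681 and 636). Without background correction the total fell from 1919 to 893, with 388 higher in HEF and 505 higher in HFF. Differences of 8-fold or more in the reported setting numbered 81 higher in HEF and 189 higher in HFF. Of the tested probes, 990 were detected in HEF but not HFF and 789 in HFF but not HEF, whatever the other lines showed. With 1 array each, these differences have no replicate check and no p-value is given. The files do not allow sex-linked transcripts to be set apart, so individual probes of this pair are not listed.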

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

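The change from H9 to HEF and the difference of HFF from NCCIT went opposite ways, by at least 2-fold each, at 265 probes, which drew attention as a difference between the 2 changes. Of these, 145 were higher in HEF than in H9 and lower in HFF than in NCCIT, and 120 were the reverse. They are 2.1% of the tested probes and stand beside 2795 that moved the same way by 2-fold or more. HFF was not derived from NCCIT, so the 2 differences are not the same transition, and HEF and HFF have 1 array each.

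The number of probes called between NCCIT and H9, 9417, is a pattern for which technical explanations were tested, with tests chosen before their results were seen. The H9 arrays were brighter than the NCCIT arrays, with median signals of 133.0 to 163.0 against 107.7 to 114.1. If brightness made the calls, the brightest and the dimmest H9 array would differ at the same probes. Of the probes called at 2-fold or more, only 0.38% differed 2-fold or more between those arrays. Those arrays differed 2-fold or more at only 31 tested probes, so a high share was not possible and the share itself decides nothing. The 31 probes show only that the span of brightness among the H9 arrays left few 2-fold differences after normalization. Neither array was as dim as those of NCCIT, so the gap between the lines was not covered. For small changes the scaling stays open, since median scaling moved the share called higher in NCCIT from 46.8% to 36.0%. The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. Of these, 1 split, the real one, gave as many calls, and the highest other split gave 0. Every other split put arrays of both lines on both sides, so the difference between the lines entered the residual spread. Low counts there were to be foreseen, and the splits cannot decide whether the grouping arose by chance.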

How the results depend on the processing

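Counts of called probes with no fold limit stayed within 1.5 times the reported ones without background correction, with saddle-point normexp, median scaling, no detection filter, an intensity trend, probes averaged per sequence record, smaller sets of arrays and each H9 or NCCIT array left out. Restricting to probes detected on all 8 arrays, which tests fewer probes, gave 6007 for NCCIT versus H9, 6152 for HEF versus H9, 4362 for the fibroblast-like cultures versus the pluripotent lines, 6037 for HFF versus H9, 5768 for HFF versus NCCIT and 5886 for HEF versus NCCIT. A 2-fold limit gave 3945, 5916 and 4376 for the first 3 of these. In the same order of the 6 comparisons, calls of 2-fold or more numbered 1878, 3545, 2591, 3299, 2969 and 3238 without background correction, which compresses folds, and 1971, 3341, 2523, 3146, 2705 and 2943 among probes detected on all 8 arrays. These counts, chosen after seeing the data, stayed within 1.5 times under the other settings. With 1 value per cell line the fibroblast-like contrast called 285 probes, on 2 residual degrees of freedom (3281 at an unadjusted p below 0.05). For HEF and HFF, 893 probes differed 2-fold or more without background correction and 650 among probes detected on all 8 arrays; leaving out an H9 or NCCIT array, or the detection filter, cannot move this count. The correlation of HEF minus H9 with HFF minus NCCIT was 0.600 without background correction, 0.571 with saddle-point normexp, 0.564 with median scaling, 0.553 with no filter, 0.597 on probes detected on all 8 arrays, 0.583 in the authors' deposited table and 0.559 to 0.563 with an array left out. The share of probes at least 2-fold apart between HFF and NCCIT that also moved in HEF was 69.9%, and in the same order of the first 5 settings 77.3%, 72.1%, 70.5%, 67.8% and 77.6%, and 69.0% to 69.9% with an array left out. HEF differed 2-fold from H9 at more probes than from NCCIT under all 11 alternatives, without background correction at 3545 against 3239. The 12 changes of individual probes that the rule took kept direction at all 174 alternative values that could be computed. They also kept the call, or the size where no test applied. The rule took the largest changes, so this was to be foreseen, and some settings repeat the reported values. Without background correction the sizes and bounds of these changes were smaller. With saddle-point normexp the bounds ran from 23.0-fold to 445-fold against 34.3-fold to 696-fold. Of the 12, 1 had a value in the authors' deposited table. With the replicate number as a block, 9286 probes were called between NCCIT and H9 against 9417; no H9 array deviated most like the NCCIT array of its own number, so the numbers are not a pairing. For the correlation, the alternatives without background correction, with saddle-point normexp, with no filter and with arrays left out were chosen after seeing the data, as were all alternatives for the share in HEF, for the order of distances of HEF and for the bounds, and for HEF and HFF saddle-point normexp and the filter on all 8 arrays. A slide block and the gene list tests were not run. The low signal over background limits small folds: a bound stands for probes undetected on the lower side.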

Other observations

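The tests in this part were chosen before their results were seen, except the odds ratio, the counts at 8-fold or more, the counts by brightness and the count of discordant replicates, which were added afterwards. The correlation of H9 minus NCCIT with HEF minus HFF, its alternatives and its split by calls between NCCIT and H9 were not among the choices made before the data were examined. Probes with large rises outnumbered those with large falls in all 3 main comparisons, although totals of called probes leaned towards falls in the reported setting. At 8-fold or more, 446 probes were higher and 164 lower in the fibroblast-like cultures than in the pluripotent lines, and higher exceeded lower under all 13 alternatives tried for that contrast. The same order held under all 14 alternatives tried for HEF against H9 and for NCCIT against H9, but the excess depends on the scaling: with median scaling 209 probes were higher and 202 lower in NCCIT than in H9, against 247 and 143, and 512 higher and 449 lower in HEF than in H9, against 572 and 364. Median scaling rests on a median below the lowest detected signal of each array. Some alternatives could hardly move these counts. Leaving out the detection filter or adding an intensity trend keeps the fitted changes, and both gave the reported counts in all 3 comparisons. For HEF against H9, so did leaving out an NCCIT array. All 3 comparisons use the H9 arrays, so they are not independent. Differences between the fibroblast-like and the pluripotent cultures were spread over the range of signal: with the tested probes ranked by mean level, 1462 called probes of 2-fold or more were among the 4246 brightest, 1763 among the 4245 in the middle and 1151 among the 4246 dimmest.

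HEF descends from H9, and a hypothesis was that differences between H9 and NCCIT would persist between HEF and HFF. They did not do so detectably over the tested probes as a whole. Across 12737 probes the difference of H9 from NCCIT and that of HEF from HFF, which share no array, correlated with r = 0.001, between -0.011 and 0.013 under the 12 alternatives tried. Simulated arrays without any change gave -0.026, which is no baseline here either, because the real lines differ. Of the 704 probes that differed at least 2-fold in both, 349 went the same way and 355 opposite ways. At the 3945 probes called at 2-fold or more between NCCIT and H9, 52.0% had the same sign and r was -0.001. At the other 8792 tested probes the values were 49.9% and 0.008. Probes detected in H9 and HEF alone outnumbered those in H9 and HFF alone 1.329 times (97 against 73), with an exact 95% interval of 0.971 to 1.826 for counting error that includes 1. It had been set beforehand that such an interval would count against common origin, but an interval that includes 1 does not exclude a surplus, so the question was left open after the result was seen. HEF also shared more probes with NCCIT alone than HFF did (85 against 55), and the odds ratio of the 4 counts was 0.86 (Fisher's exact 95% interval 0.53 to 1.39), so a surplus for H9 over NCCIT was not detectable. A test for a contribution of array brightness had nothing to remove, with a correlation of 0.000 after taking out the trend with intensity. Common origin therefore stays open for a small number of probes, and the intervals cover counting error only. Sex-linked transcripts could not be set apart here either, so any such transcripts are among these counts.

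Some sequence records carry a probe with the suffix A and a probe with the suffix I, which in the array maker's naming, not given in the sources used here, stand for all isoforms and for a particular isoform. Of 732 such records, 72 had both probes detected on all H9 and NCCIT arrays, and at 42 of them (58.3%) the ratio of the 2 probes within an array differed between NCCIT and H9 (limma adjusted p below 0.05), 14 by 2-fold or more. Compression of dim probes towards the background would shrink the change of the dimmer probe and not turn it. At 7 records both probes were called and in opposite directions, and at 19 of the 42 the dimmer probe changed more. These make up 24 records for which the values in the reported scaling argue against compression, and it stays open for the other 18. The direction and relative size of small changes depend on the scaling, and the pairs were not tested again with median scaling. At 2 of the 7 both changes exceeded 1.5-fold. Of the 10 splits of the 6 arrays, 1, the real one, gave 42 or more unequal pairs and the highest other split gave 0, but 10 splits are too few for a share under 0.05. The other splits mixed the lines here too, which raises the residual spread, so they cannot decide whether array noise made the pairs unequal. A difference in isoform use between NCCIT and H9 may account for such records, and so may cross-hybridisation of either probe, which was not tested.

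Replicates of NCCIT disagreed by over 4-fold at 1 probe, which read 936.6 on 1 array, where it was detected, and as little as 78.8 on the arrays where it was not. No tested probe of H9 disagreed by as much, and the greatest range among H9 replicates was 1.73 on the log2 scale.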
